A study of Mus musculus with 10 samples.

How the data were processed

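Total RNA of splenic monocytes from C57BL/6 mice aged 3 months was measured on 10 Illumina mouse expression arrays. The 5 TCL1-AT samples came from mice 6 weeks after transplantation with murine chronic lymphocytic leukaemia (CLL) cells of Eµ-TCL1 mice, a strain whose B cells carry a TCL1 transgene, and the 5 WT samples came from matched control mice. Per the labels' protocols, cells were sorted as lineage negative, CD11b positive, intermediate for F4/80, low to intermediate for CD11c and low for MHC class II. RNA was extracted with a column kit, and biotin-labelled cRNA was made from 150 ng of total RNA. The labels call the WT samples pools and do not say how many mice a pool holds, or whether each TCL1-AT sample came from its own mouse. The p-values below therefore measure the spread between these samples only.

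Per the file headers, the deposited non-normalized table gives for each array a signal intensity and a detection p-value for each of 46237 probes. The intensity values are linear, positive, not background-subtracted and not normalized, as found from the values. The deposited detection p-value falls as the signal of its own array rises, and every detection column ranked the signal of its own array best. The authors' series matrix holds log2 values of the same arrays. Its scale, centring and direction are not given in the sources used here and were found from the values: it differed from normexp correction and quantile normalization of the intensity table by at most 0.00043 on the log2 scale, with a median of 4.30 on every array. The scanner and its software are not given in the sources used here. Every column of values in both tables belonged to 1 of the 10 samples, and no pair of arrays held identical values.

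Signals were corrected with the neqc method of limma 3.58.1 in R 4.3.3, which fits normexp with negative control levels inferred from the detection p-values, adds an offset of 16, and applies quantile normalization and log2. Probes with a detection p under 0.05 on at least 5 arrays were kept, which left 20241 probes. Genes were named from the array platform's annotation, in which 35784 probes had 1 symbol, 0 had several and 10453 were not listed and stay unnamed here. Symbols were updated through the Entrez identifier for 28620 probes and through the transcript accession for 2637, using a RefSeq gene table of assembly GRCm38.p6 for names only, and 4527 probes kept the platform's symbol. No coordinates are given, because no genome build is given for the probes. Each gene was represented by its probe with the highest mean over all arrays, and 3353 unnamed probes were kept as themselves beside 11506 named genes, which made 14859 features. Among the named genes, 3703 had more than 1 tested probe, and 28 called genes had another probe called in the opposite direction. Of the genes named in the report, 1 further probe was not called for each of Spn, Gbp2, Adgre1, Hbb-b1, Cpa3, Fcrla, Spib and Pgk1, and for Cgnl1, Cd80, Fcgr2b, Ctsa, Cd8b1 and Dpp4 the other probes are described beside the gene. Other probes called in the same direction gave log2 differences down to 2.80 for Whrn, 2.07 for Nr1h3, 1.05 for Gbp5, 1.01 for Cxcl10, 0.81 for Nfkbia, 0.35 for Asns, -0.50 for Fn1 and -0.66 for Abca9, and those of Ifnlr1, Cldn10 and H2-Eb2 stand beside the gene.

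TCL1-AT and WT were compared with limma's lmFit and eBayes, 2-sided, and a feature was called at a Benjamini-Hochberg adjusted p under 0.05. Log2 differences are TCL1-AT minus WT, each with its standard error (SE), and group levels are mean normalized log2 signals ± SD over 5 arrays per group. Folds of dim probes understate the change, because the offset compresses low signals, so only the log2 difference is given for genes detected on some but not all arrays of a group. For a gene not detected on any array of a group the fold is a bound, taken against the higher of its own signal and the lowest detected signal on those arrays. The share of detected probes and the raw signal were compared with exact permutation tests, 2-sided, whose smallest possible p is 0.00794 with 5 arrays against 5. For arrays, their number limits the precision.

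Before the data were examined, 37 gene lists were written: monocyte identity, immune and metabolic pathways, ribosomal proteins and markers of other cell types that the sort could hold, with a further list of 10 surface marker genes, namely those of the sorting gate with Csf1r, Ly6c2 and Cd274 added. Lists with at least 3 tested members, 35 in all, were tested with limma's camera, which sets the members against all other features, with a preset correlation of 0.01 between genes and adjustment over the lists. The estimated correlation and the fry test were run beside it. The rule for named genes was fixed at the same time: the 12 largest rises and 12 largest falls among called genes with no overlap between the groups, leaving out unnamed gene models, up to 4 members of each list with the lowest p, all genes of the surface marker list, and the 3 members of each other cell type list with the highest mean signal. The text names part of the genes this rule takes from the lists. Irf8, Ido1, H2-DMa, Mcm4, Pdcd1lg2, Havcr2 and Vsir were named after their values were seen, as were the genes and the 9 lists described under other observations only.

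The procedure was tested on simulated data made from the 5 against 5 comparison of 14859 features. It called 28 of 67 genes changed by 0.5 on the log2 scale, 62 of 67 changed by 1 and 66 of 66 changed by 2, with 10 unchanged genes called. It also called 10 of 10 lists shifted by 0.5 and 1 of 50 unshifted lists. The simulated genes varied independently of each other, so these list counts do not cover lists whose genes are correlated.

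The alternatives planned before the data were examined were no background correction, normexp without detection p-values, median scaling, cyclic loess, the authors' series matrix, no detection filter, a strict filter (detection p under 0.01 on all 10 arrays), the mean over a gene's probes, every probe by itself, the replicate number as a block, array weights by group or by array, eBayes with a trend and robust variances, a fold threshold, other set tests, and leaving out each array. Chosen after the data were seen were a block or a covariate for raw background level, leaving out TCL1-AT 3 and TCL1-AT 4 together, and median scaling over probes detected on all arrays, as were exact permutation tests of each list's mean per array, adjusted over the lists. A slide block was planned but not run, since no slide is named in the headers or labels.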

Results

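Gene expression was measured in sorted splenic monocytes of leukaemic mice (TCL1-AT, 5 samples) and of control mice (WT, 5 samples labelled as pools). The leukaemic mice were taken 6 weeks after transplantation of Eµ-TCL1 leukaemia cells, and no transplantation is given for the control mice. The comparison addresses how monocytes of a spleen with CLL differ in their transcripts from monocytes of a control spleen. TCL1-AT arrays detected 44.5% ± 0.875 of 46237 probes (SD, n = 5) and WT arrays 44.3% ± 1.01 (SD, n = 5), a difference of 0.261 percentage points (exact permutation p = 0.667), or -0.0776 without WT 5. The median raw signal was 91.8 ± 1.19 intensity units in TCL1-AT and 85.0 ± 4.99 in WT (SD, n = 5 each, exact permutation p = 0.0317). The 5 TCL1-AT arrays (90.3 to 93.4) and WT 1 (92.1) lay above WT 2 to 5 (80.4 to 87.8). Mean signal was 2.95 to 3.90 times the estimated background on the 10 arrays.

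After normalization the groups separated on the first principal component, which held 53.3% of the variance, with TCL1-AT arrays at 21.2 to 33.7 and WT arrays at -32.3 to -22.5. The second component (13.8%) set TCL1-AT 4 apart at -32.5, with the other arrays at -14.6 or above. Correlations across features were 0.983 to 0.993 within TCL1-AT, 0.987 to 0.992 within WT and 0.964 to 0.977 between the groups.

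**Figure D1:**
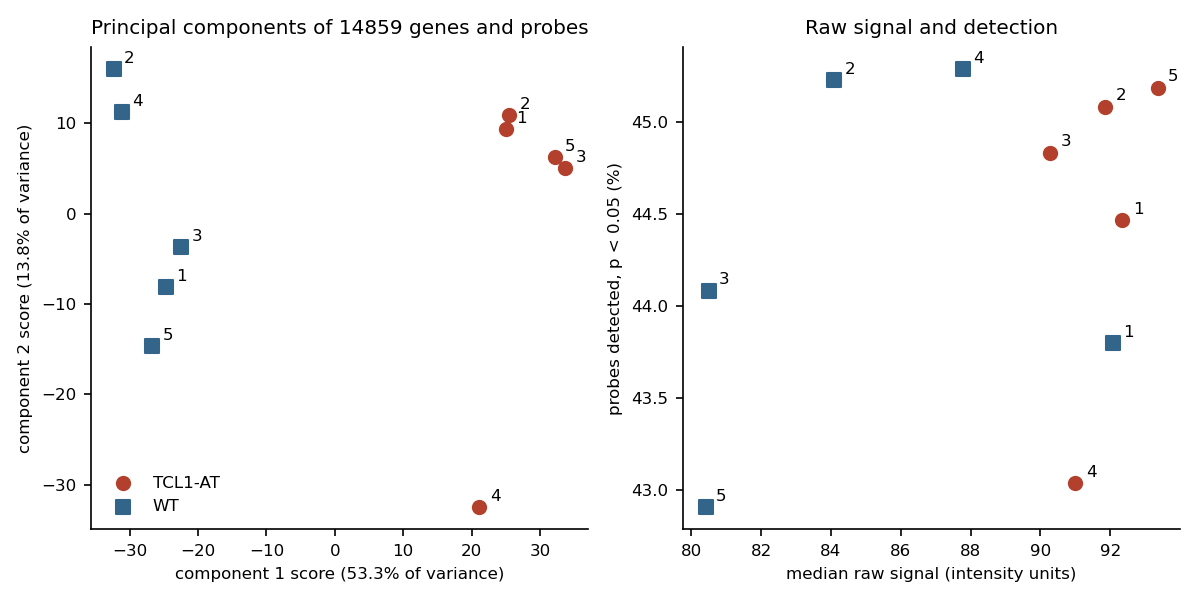
Left, scores of the 10 arrays on the first and second principal components of normalized log2 signals; right, median raw signal (intensity units) against the share of probes detected (%). Each point is an array numbered by replicate, circles are TCL1-AT and squares WT; component 1 parts the groups, TCL1-AT 4 lies at -32.5 on component 2, and WT 1 shares the higher raw signal (92.1) of the TCL1-AT arrays.

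Monocytes from leukaemic spleens carried far more transcript of several enzymes and immune regulators than control monocytes. Upp1, which encodes a uridine phosphorylase, was 76.6-fold higher, with a log2 difference of 6.26 (SE 0.14, adjusted p = 9.9e-12). Il4i1, a secreted amino acid oxidase, was 33.8-fold higher, Mmp14, a membrane-bound matrix metalloproteinase, 31.3-fold, and Acod1, the enzyme that makes itaconate, 26.0-fold. Ddit4, an inhibitor of mTORC1, showed the largest named fall, with a log2 difference of -3.46 (SE 0.32, adjusted p = 4.75e-06). Trem2, a lipid-sensing receptor, was 5.05-fold lower, Apoe, an apolipoprotein, 4.60-fold and Lpl, lipoprotein lipase, 4.19-fold.

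The other genes among the 12 largest rises were Whrn (log2 difference 4.46), H2-Eb1 (3.80), Ifnlr1 (3.73), Il10 (3.69), Pecam1 (3.40), Traf1 (3.31), Cldn10 (3.29) and Nr1h3 (3.06). Il10, an anti-inflammatory cytokine, stood at 7.98 ± 0.63 in TCL1-AT and 4.29 ± 0.12 in WT (log2 signal, SD, n = 5 each). Nr1h3, which encodes the oxysterol receptor LXR alpha, stood at 10.93 ± 0.12 and 7.87 ± 0.19. The other genes among the 12 largest falls were Trf (-2.63), Cgnl1 (-2.37), Cd93 (-2.21), Irf4 (-2.07), Timp2 (-2.06), Mlxipl (-2.05), Mrc1 (-2.05) and Abca9 (-2.02). Another probe of Cgnl1 gave 0.27, and the lowest of the other probes gave 0.55 for Ifnlr1 and 1.07 for Cldn10. All 24 genes had no overlap between the 5 TCL1-AT and the 5 WT values, and adjusted p-values from 9.9e-12 to 0.00011 in limma's test.

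In all, 1828 features (12.3% of 14859) were called higher and 2291 (15.4%) lower in TCL1-AT. A log2 difference of at least 1 was reached by 270 of the higher and 260 of the lower features, and 62 rose and 14 fell at least 4-fold. The groups did not overlap for 20.5% of all features, where chance gives 0.794%. Median scaling called 991 higher, and a block for raw background level, chosen after the data were seen, called 452 higher and 565 lower, an estimate that rests on WT 1, the only WT array among the arrays of higher signal. Background as a covariate called 766 and 1048. Among the named genes the block ended 27 calls, at 0.63 to 1.33 times their log2 difference and with standard errors 1.62 to 1.81 times as large, and the values given below for lost calls are log2 differences with the block.

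**Figure D2:**
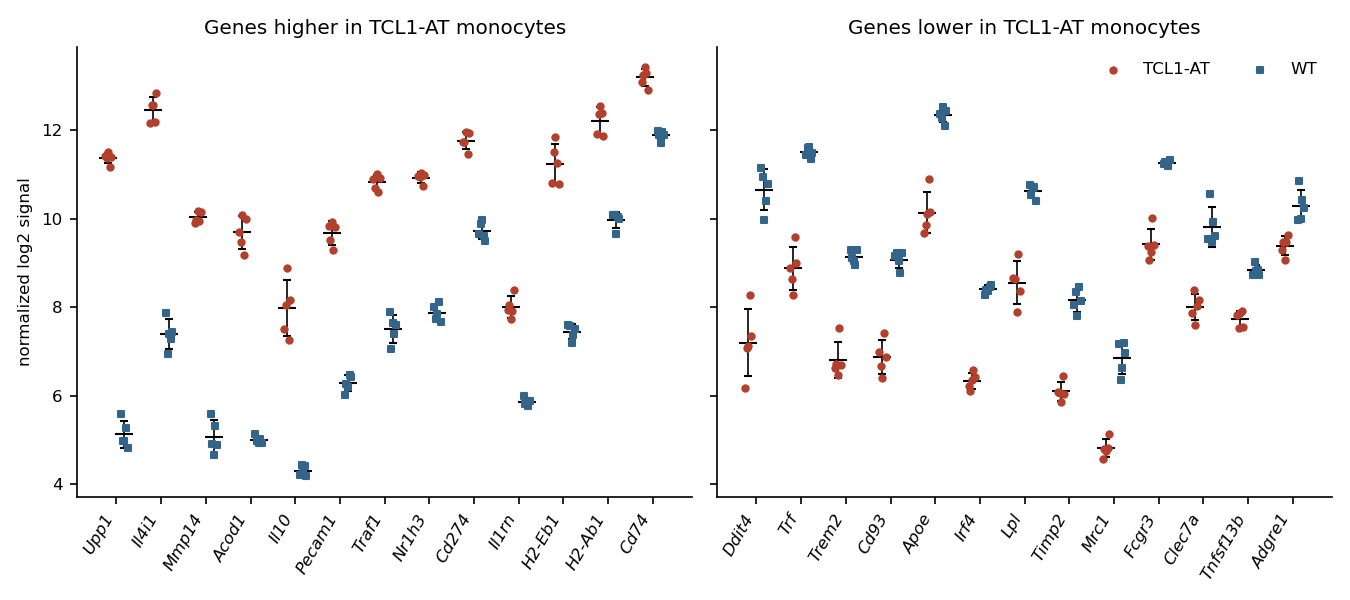
Normalized log2 signal (y axis) of genes called higher (left) and lower (right) in TCL1-AT monocytes. Points are arrays, circles TCL1-AT and squares WT, bars are the mean and SD of 5 arrays, and Upp1 at 11.38 against 5.12 and Ddit4 at 7.20 against 10.65 are the widest named differences in each panel.

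Among genes of the sorting gate, those of MHC class II were much higher in leukaemic monocytes, although the cells had been sorted as low for MHC class II. H2-Eb1 was 13.9-fold higher, H2-Ab1 4.75-fold, H2-Aa 4.62-fold and Cd74, the invariant chain, 2.47-fold. Cd274, which encodes the checkpoint ligand PD-L1, was 4.13-fold higher, at 11.77 ± 0.20 against 9.73 ± 0.19 (SD, n = 5 each). Adgre1, which encodes F4/80, fell 1.88-fold, a call lost with the background block (-0.59, adjusted p = 0.253), and Itgax, which encodes CD11c, rose by 0.39, a call also lost with that block (0.41, adjusted p = 0.371) and when any 1 of 7 arrays was left out. Itgam, which encodes CD11b, differed by -0.19 (adjusted p = 0.354) and the macrophage growth factor receptor gene Csf1r by -0.29 (adjusted p = 0.185), and neither was called. Ly6c2 was not tested. Of these 10 genes, of which Csf1r, Ly6c2 and Cd274 are not part of the gate, 9 were tested, 6 rose and 1 fell, and the counts adjusted over the list alone were 6 and 1.

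Most of the antigen presentation genes tested were higher in leukaemic monocytes. Of 11 MHC class II presentation genes, 9 rose and 1 fell (9 and 1 adjusted over the list alone), with a mean log2 difference of 1.53 (camera adjusted p = 3.5e-08, and adjusted p = 0.127 with an estimated correlation). Ciita, the master activator of class II transcription, was 2.88-fold higher and H2-Eb2 rose by 2.31 on the log2 scale (0.69 at its lowest probe), while H2-DMa, which helps load peptides on class II, fell by 0.41 on the log2 scale, a call lost with the background block (-0.54, adjusted p = 0.12). The mean of this list was 9.40 to 9.91 on the TCL1-AT arrays and 7.97 to 8.17 on the WT arrays, and was highest on TCL1-AT 3, which also had the highest mean of B cell markers. Of 15 MHC class I presentation genes, 13 rose and 0 fell (13 and 0 adjusted over the list alone), at a mean of 0.55 (camera adjusted p = 4.3e-07, and adjusted p = 0.0763 with an estimated correlation). Nlrc5, an activator of class I transcription, rose by 1.08, the peptide transporter gene Tap1 by 0.90 and the immunoproteasome gene Psmb9 by 0.84.

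Interferon-induced genes were higher in leukaemic monocytes. In the type I interferon response list, 18 of 22 genes rose and 0 fell (19 and 0 adjusted over the list alone), at a mean log2 difference of 0.75 (camera adjusted p = 1.6e-10, and adjusted p = 0.0876 with an estimated correlation). Isg15, a ubiquitin-like modifier, was 2.99-fold higher, Oas2, a sensor of double-stranded RNA, 2.62-fold and Ifit3 2.27-fold. In the list of interferon-gamma induced GTPases and effectors, 10 of 16 genes rose and 2 fell (11 and 2 adjusted over the list alone), at a mean of 0.77 (camera adjusted p = 2.3e-05, and adjusted p = 0.158 with an estimated correlation). The GTPase genes Gbp5, Gbp2 and Igtp were 4.10-fold, 2.52-fold and 2.27-fold higher. Irf8, a transcription factor of monocyte development, fell by 0.85 and Ido1, a tryptophan-degrading enzyme, by 0.77, and the call of Irf8 was lost with the background block (-0.54, adjusted p = 0.218).

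Targets of NF-kB formed the list with the lowest p in camera, where in fry that was immune inhibitory molecules. Of 15 tested, 14 rose and 0 fell (14 and 0 adjusted over the list alone), at a mean log2 difference of 1.22 (camera adjusted p = 4.0e-12, and adjusted p = 0.0737 with an estimated correlation). Traf1, an adaptor of TNF receptor signalling, was 9.93-fold higher, Nfkbia, the NF-kB inhibitor, 2.74-fold, Sod2, a mitochondrial superoxide dismutase, 2.44-fold and the adhesion molecule gene Icam1 2.37-fold.

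Immune inhibitory molecules moved in both directions. Of 14 tested, 5 rose and 4 fell (5 and 5 adjusted over the list alone), with a mean of 0.82, a median of 0.11 and a camera adjusted p of 0.115. Il4i1, Il10, Cd274, Pdcd1lg2 (log2 difference 1.68), which encodes PD-L2, and Il1rn (4.45-fold), the interleukin-1 receptor antagonist, made up the rises. Vsir, a checkpoint ligand gene, fell by 1.12 and Havcr2, which encodes TIM-3, by 0.78, and both calls were lost with the background block (-0.82 and -0.53, adjusted p = 0.0716 and 0.122). With that block the list itself passed (camera adjusted p = 0.0267). Of 6 T cell co-stimulatory ligands, 1 rose and 3 fell (1 and 3 adjusted over the list alone, mean -0.18, camera adjusted p = 0.491), with Cd40 2.45-fold higher and Cd80 1.68-fold lower, although another probe of Cd80 gave -0.03.

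Of 10 pro-inflammatory cytokine genes, 4 rose and 0 fell (4 and 0 adjusted over the list alone, mean 0.48). The camera adjusted p was 0.0812, and 0.0470 without TCL1-AT 3. Il1b was 4.34-fold and Tnf 2.63-fold higher. Of 8 chemokine genes, 4 rose and 2 fell (4 and 2 adjusted over the list alone, mean 0.58, camera adjusted p = 0.109). The interferon-induced T cell attractants Cxcl9 and Cxcl10 were 4.65-fold and 4.66-fold higher and Cxcl16 2.88-fold higher, while Ccl6 was 2.80-fold lower. Among 15 chemokine receptors and adhesion molecules, 3 rose and 3 fell (4 and 5 adjusted over the list alone), with a mean of 0.09, a median of -0.05 and a camera direction of down (adjusted p = 0.835), against an upward direction in fry (adjusted p = 0.28). Ccrl2, a chemerin-binding receptor, was 5.75-fold higher, and Cxcr3 fell by 0.90 on the log2 scale.

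**Figure D3:**
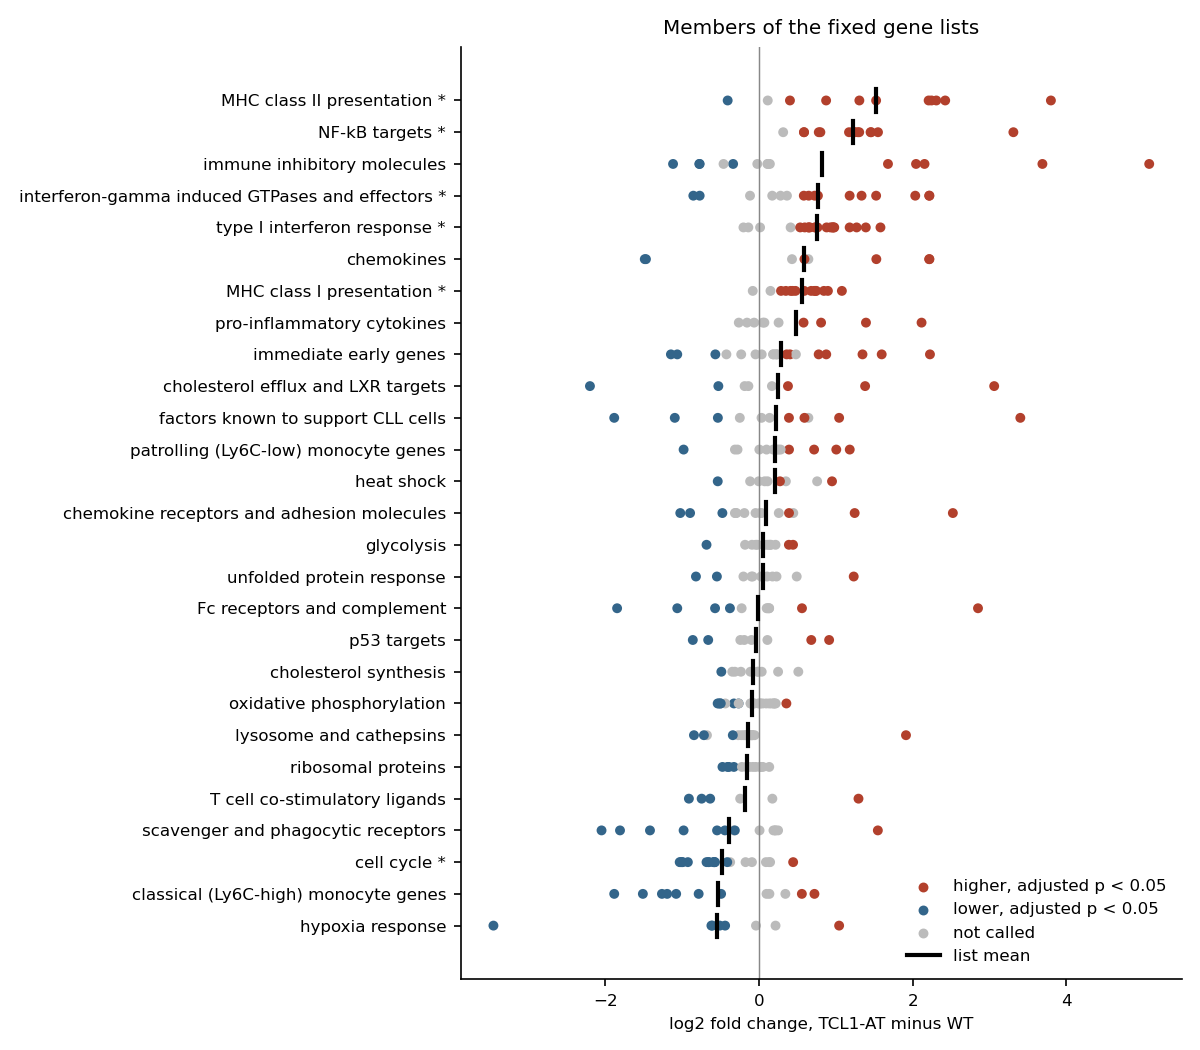
Log2 difference between TCL1-AT and WT (x axis) of the tested members of each fixed list (y axis) other than markers of other cell types. Points are genes, red if called higher, blue if called lower and grey otherwise, black bars are list means, and asterisks mark lists with a camera adjusted p under 0.05; NF-kB targets had 14 of 15 members higher and cell cycle genes 13 of 20 lower.

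Genes of both monocyte subsets included rises and falls, with more rises in the patrolling list and more falls in the classical list. Of 13 genes of patrolling (Ly6C-low) monocytes, 4 rose and 1 fell (4 and 1 adjusted over the list alone, mean 0.21, camera adjusted p = 0.115). Spn, which encodes CD43, was 2.27-fold, Eno3 2.01-fold and Treml4 1.64-fold higher. The scavenger receptor gene Cd36 was not detected on any TCL1-AT array and was at least 1.74-fold lower (adjusted p = 0.00027). Of 12 genes of classical (Ly6C-high) monocytes, 2 rose and 7 fell (2 and 7 adjusted over the list alone, mean -0.53). The camera adjusted p was 0.0817, and 0.0359 without TCL1-AT 4. In exact permutation tests of array means, chosen after the data were seen, the classical list was lower without overlap (adjusted p = 0.0132). The patrolling list was higher there, with overlap between the groups (adjusted p = 0.0242). Of all 35 lists, 26 had an adjusted p under 0.05 in these tests. Fry gave adjusted p = 0.0049 for the classical and 0.0070 for the patrolling list. Fn1, fibronectin, was 3.69-fold and Ifitm6 2.29-fold lower, while haptoglobin (Hp) was 1.65-fold higher.

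Among receptors for uptake, more genes fell than rose. Of 14 scavenger and phagocytic receptors, 1 rose and 7 fell (1 and 7 adjusted over the list alone, mean -0.39, camera adjusted p = 0.0817). The mannose receptor gene Mrc1 was 4.14-fold and the beta-glucan receptor gene Clec7a 3.51-fold lower, and Clec4e, which encodes Mincle, was 2.92-fold higher. Of 11 Fc receptor and complement genes, 2 rose and 4 fell (2 and 4 adjusted over the list alone), with a mean of -0.02, a median of 0.10 and a downward camera test (adjusted p = 0.572). The antibody receptor genes Fcgr3 and Fcgr2b were 3.60-fold and 2.09-fold lower, with 2 of 5 probes of Fcgr2b not called, and complement factor B (Cfb) was 7.22-fold higher. Of 16 lysosome and cathepsin genes, 1 rose and 3 fell (1 and 4 adjusted over the list alone, mean -0.14, camera adjusted p = 0.0817). Npc2 fell by 0.85, a call lost with the background block (-0.71, adjusted p = 0.147), and Hexa by 0.72. The brightest probe of Ctsa rose by 1.91, but its other probes reached down to -0.42 and their mean of 0.21 was not called.

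Of 11 factors known to support CLL cells, 4 rose and 3 fell (4 and 3 adjusted over the list alone, mean 0.23, camera adjusted p = 0.572). Pecam1, the adhesion molecule CD31, was 10.6-fold higher, while Tnfsf13b, the B cell survival factor BAFF, was 2.14-fold lower at 7.74 ± 0.19 against 8.83 ± 0.12 (SD, n = 5 each). Vegfa rose by 1.04, a call lost with the background block (1.13, adjusted p = 0.117).

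Cell cycle genes were lower in leukaemic monocytes. Of 20 tested, 13 fell and 1 rose (14 and 1 adjusted over the list alone). The mean log2 difference was -0.48 (camera adjusted p = 0.00025, and adjusted p = 0.409 with an estimated correlation). It lay between -0.526 and -0.407 with each array left out. The list's mean was 7.01 and 7.12 on WT 3 and WT 4, 6.65 to 6.73 on the other WT arrays and 6.23 to 6.52 on TCL1-AT arrays. WT 3 and WT 4 also had the highest means of neutrophil markers, 9.54 and 9.63. Aurkb, Nusap1, Kif11 and Mki67, genes of mitosis or proliferating cells, fell by 1.03, 1.02, 1.00 and 0.99, while Mcm4, a part of the replicative helicase, rose by 0.44. With the background block the list's mean was -0.34 and its camera adjusted p 0.0509, and the calls of Nusap1, Kif11, Mki67 and Mcm4 were lost (-0.90, -0.64, -0.81 and 0.47, adjusted p = 0.0542, 0.247, 0.124 and 0.0854).

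The remaining pathway lists and ribosomal proteins did not pass in camera, which sets a list against all other features. Some still differed between the groups. Array means did not overlap for LXR targets, immediate early genes, hypoxia response, oxidative phosphorylation and ribosomal proteins (exact permutation adjusted p = 0.0132 each). They overlapped for p53 targets, the unfolded protein response, glycolysis, cholesterol synthesis and heat shock. Of 8 genes of cholesterol efflux and LXR targets, 3 rose and 2 fell (3 and 2 adjusted over the list alone, mean 0.24, camera adjusted p = 0.5), where Nr1h3 and the phospholipid transfer gene Pltp (2.61-fold) were higher and Apoe lower. Of 20 immediate early genes, 7 rose and 3 fell (7 and 3 adjusted over the list alone, mean 0.28, camera adjusted p = 0.0817), with Jun 4.68-fold, Egr1 3.03-fold and Ier3 2.55-fold higher and Atf3 2.21-fold lower. Of 8 hypoxia response genes, 1 rose and 5 fell (1 and 5 adjusted over the list alone, mean -0.55, camera adjusted p = 0.11). Of 8 p53 targets, 2 rose and 2 fell (2 and 2 adjusted over the list alone, mean -0.04, camera adjusted p = 0.717), with Cdkn1a, the cell cycle inhibitor p21, rising by 0.91 and Trp53inp1 falling by 0.86, and the mean was -0.0737 without WT 3 and -0.0007 without WT 4. Of 12 genes of the unfolded protein response, 1 rose and 2 fell (1 and 2 adjusted over the list alone, mean 0.05, camera adjusted p = 0.835), and the rise was in Asns, asparagine synthetase, at 2.35-fold. Without TCL1-AT 1 the mean of this list was 0.0193, and without TCL1-AT 3 it was 0.078.

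Of 14 glycolysis genes, 2 rose and 1 fell (1 and 1 adjusted over the list alone, mean 0.05, camera adjusted p = 0.572), and the mean was 0.0108 without TCL1-AT 4 and 0.0763 without TCL1-AT 5. Pgk1 fell by 0.68, a call lost with the background block (-0.43, adjusted p = 0.284). Of 24 genes of oxidative phosphorylation, 1 rose and 6 fell (1 and 6 adjusted over the list alone, mean -0.09, camera adjusted p = 0.5). Cholesterol synthesis had 10 tested genes, of which 0 rose and 1 fell (0 and 1 adjusted over the list alone, mean -0.07, camera adjusted p = 0.589). Heat shock had 9 tested genes, of which 2 rose and 1 fell (2 and 1 adjusted over the list alone, mean 0.21, camera adjusted p = 0.355), and the mean without TCL1-AT 1, where the list was highest, was 0.0329. Ribosomal proteins had 13 tested genes, of which 0 rose and 4 fell (0 and 4 adjusted over the list alone, mean -0.16, camera adjusted p = 0.107).

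Markers of other cell types moved in different directions. T cell transcripts were lower in the leukaemic samples, where Cd3d, Cd3g and Cd3e, which encode chains of the T cell receptor complex, were 2.72-fold, 2.22-fold and 2.18-fold lower. Of 9 T cell markers, 0 rose and 6 fell (0 and 7 adjusted over the list alone), at a mean log2 difference of -0.72 (camera adjusted p = 7.6e-05, and adjusted p = 0.0876 with an estimated correlation). Cd8b1 differed by -0.23 at its brightest probe and was not called there, but the mean of its probes fell by 1.24 and was called. Erythroid transcripts were higher, with 4 of 5 markers rising and 0 falling (4 and 0 adjusted over the list alone), at a mean of 1.49 (camera adjusted p = 0.0049, and adjusted p = 0.185 with an estimated correlation). The globin genes Hbb-b1 and Hba-a1 were 4.88-fold and 4.42-fold higher and Slc4a1, the red cell anion exchanger, rose by 2.01 on the log2 scale. The calls of both globins were lost with the background block (1.97 and 1.82, adjusted p = 0.145 and 0.175), while the list passed with it at a mean of 1.32 (camera adjusted p = 0.0229). With the strict detection filter fewer than 3 erythroid markers were left, and the list was not tested.

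Of 6 B cell and CLL markers, 3 rose and 0 fell (3 and 0 adjusted over the list alone, mean 0.25, camera adjusted p = 0.324). The B cell receptor gene Cd79b rose 1.51-fold, and Spib and Fcrla rose by 0.66 and 0.93 on the log2 scale (Fcrla by 0.62 without TCL1-AT 3). All 3 calls were lost with the background block (0.44, 0.62 and 1.21, adjusted p = 0.336, 0.0621 and 0.162), with which the list's mean was 0.278. Igh-6, the immunoglobulin mu heavy chain, stood at 10.73 ± 0.62 against 11.21 ± 0.12 (SD, n = 5 each, adjusted p = 0.145) and fell by 0.72 without TCL1-AT 3 (adjusted p = 0.0062), and Cd22 differed by -0.21 (adjusted p = 0.357). TCL1-AT 3 had the highest mean of these markers, 7.27 on the log2 scale, against 6.45 to 6.64 on the other TCL1-AT arrays and 6.43 to 6.61 on the WT arrays, and without it the list's mean difference was 0.109.

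Of 3 basophil and mast cell markers, 2 rose and 0 fell (3 and 0 adjusted over the list alone, mean 1.14, camera adjusted p = 0.0817). Fcer1a, a chain of the IgE receptor, stood at 7.28 and 7.36 on TCL1-AT 1 and 5 and at 4.88 to 5.62 on the other TCL1-AT arrays. Cpa3 stood at 6.34 and 6.52 on these 2 arrays and at 4.72 to 4.95 on the other TCL1-AT arrays. Its fold bound, given below, was 1.88 without TCL1-AT 5. The same 2 arrays had the 2 highest means among TCL1-AT arrays in 10 of the 35 lists, for example basophil and mast cell markers (7.59 and 7.66, others in TCL1-AT 5.85 to 6.13), pro-inflammatory cytokines (7.68 and 7.67, others 7.46 to 7.52), chemokines (8.91 and 8.85, others 8.43 to 8.57) factors known to support CLL cells (7.37 and 7.41, others 7.07 to 7.14) and erythroid markers (7.69 and 7.99, others 7.20 to 7.58), and the remaining 5 were immediate early genes, heat shock, hypoxia response, chemokine receptors and adhesion molecules, and neutrophil markers. The mast cell protease gene Cpa3 was not detected on any WT array and was at least 2.26-fold higher, and both calls were lost with the background block (1.32 and 1.10, adjusted p = 0.357 and 0.309), with which the list's mean was 1.04. The only tested eosinophil marker, the granule protein gene Prg2, rose 6.43-fold, a call lost with that block (1.91, adjusted p = 0.0804). Neither of 2 platelet and megakaryocyte markers was called (0 rose and 0 fell adjusted over the list alone, mean -0.16), and these lists were too small to test.

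Of 5 NK cell markers, 1 rose and 0 fell (1 and 0 adjusted over the list alone, mean 0.33, camera adjusted p = 0.44), and the rise was in Prf1, perforin, at 2.79-fold, a call lost with the background block (1.36, adjusted p = 0.124). Of 14 neutrophil markers, 0 rose and 3 fell (0 and 3 adjusted over the list alone, mean -0.21, camera adjusted p = 0.194). Cd177 was 2.85-fold and the growth factor receptor gene Csf3r 1.63-fold lower, the latter not called with the block (-0.54, adjusted p = 0.22), and the abundant calprotectin genes S100a8 and S100a9 differed by -0.08 and -0.14 (adjusted p = 0.757 and 0.599). Of 9 dendritic cell markers, 3 rose and 2 fell (4 and 3 adjusted over the list alone, mean 0.33, camera adjusted p = 0.44). The transcription factor gene Zbtb46, detected on 1 of the 5 WT arrays, rose by 1.57 on the log2 scale and Dpp4 was 4.12-fold higher, though another probe of Dpp4 gave -0.20, and Cd209a was 1.88-fold lower, a call lost with the block (-0.95, adjusted p = 0.125). Of 10 splenic macrophage markers, 1 rose and 4 fell (1 and 4 adjusted over the list alone, mean -0.05, camera adjusted p = 0.689), with Spic, a factor of red pulp macrophages, 3.16-fold higher and the iron exporter gene Slc40a1 1.89-fold lower, the latter not called with the block (-0.90, adjusted p = 0.209). The mean of the macrophage list was -0.0714 without TCL1-AT 1 and -0.0212 without TCL1-AT 4.

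**Figure D4:**
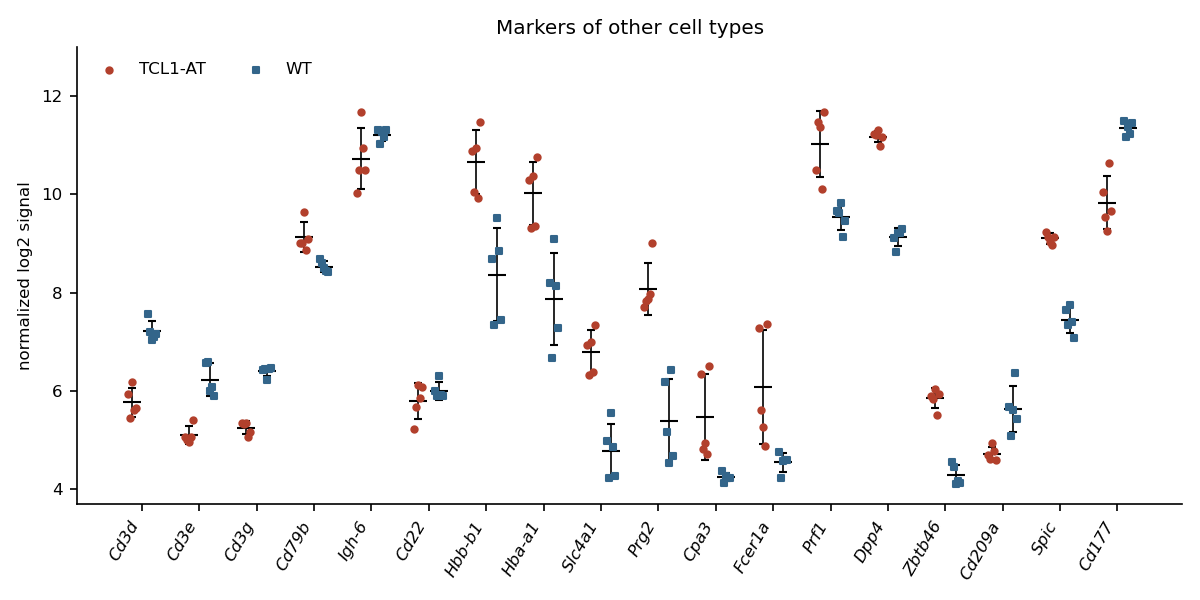
Normalized log2 signal (y axis) of marker genes of other cell types. Points are arrays, circles TCL1-AT and squares WT, and bars are the mean and SD of 5 arrays; Cd3d stood at 5.77 in TCL1-AT against 7.22 in WT and Hbb-b1 at 10.66 against 8.37.

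In all, 8 of the 35 tested lists passed in camera, 6 upward and 2 downward, 0 passed in camera with an estimated correlation, where 8 had an unadjusted p under 0.05, and 22 passed in fry. The array means of 21 of the 35 lists, all 8 among them, did not overlap between the groups, and 26 lists had an adjusted p under 0.05 in exact permutation tests of these means, chosen after the data were seen (adjusted p = 0.0132 for each of the 8).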

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

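The counts over other splits of the arrays were planned before the data were examined. The tests with held-out arrays, with a block for raw background level, and with markers of B cells, T cells and erythroid cells, and the exact tests of list means, were chosen after the results were seen.

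The 136 named genes and 3 array measures gave 278 groups of 5 values, and in 25 of them an array lay apart from the others by more than Dixon's 95% critical gap. Chance flags about 1 in 20 groups, which is 13.9 of 278. TCL1-AT 4 held 6 of them, with log2 levels of 10.73 for Nr1h3 (others 10.95 to 11.04), 7.52 for Trem2 (6.46 to 6.72), 10.78 for Oas2 (11.33 to 11.55), 10.17 for Fcgr2b (9.83 to 9.87), 4.75 for Mlxipl (4.10 to 4.28) and 13.06 for S100a8 (13.70 to 13.90). TCL1-AT 3 stood above its group in the B cell markers Cd79b, at 9.65 (others 8.88 to 9.09), and Fcrla, at 6.54 (4.87 to 5.08). TCL1-AT 5 stood out in Cd3e at 5.41 (4.96 to 5.07) and Prg2 at 9.02 (7.70 to 7.98), and TCL1-AT 2 in Csf1r at 11.83 (11.40 to 11.51) and Ier3 at 8.24 (8.51 to 8.57).

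Among WT arrays, WT 1 lay apart in Cxcl9 at 7.47 (others 6.86 to 7.03), Abca9 at 7.96 (8.25 to 8.36) and Asns at 4.45 (5.06 to 5.30). WT 2 lay apart in Ifitm6 at 12.66 (12.01 to 12.17), Ccl6 at 10.53 (10.09 to 10.17) and Npc2 at 10.60 (10.07 to 10.22). WT 3 lay apart in H2-Ab1 at 9.65 (10.00 to 10.09), Cd22 at 6.30 (5.89 to 6.01) and Cd3g at 6.23 (6.42 to 6.46). WT 4 lay apart in Vegfa at 4.69 (4.09 to 4.17), Slc40a1 at 6.87 (6.11 to 6.30) and Ier3 at 6.72 (7.19 to 7.34), and WT 5 in Fcgr2b at 11.10 (10.93 to 10.96).

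The size of the group difference was the first pattern weighed. Of 100 splits of the 10 arrays into 5 and 5, only 1, the real one, called as many features as the 1828 higher (highest other 70) and only 1 as many as the 2291 lower (highest other 70). Chance is therefore unlikely for both counts, as far as 100 splits can tell. For the number of lists past the threshold, 8, chance is not excluded, since 27 of 100 splits, the real one included, reached 8 or more (highest other 14). Of the 26 others, 20 exchanged a single array of each group and so kept most of the real contrast. The array means of each of these 8 lists did not overlap between the groups (exact permutation adjusted p = 0.0132, from the smallest p this test can give), which makes chance unlikely for their differences. The means of 21 of the 35 lists did not overlap, so this test does not set the 8 apart. Raw background level, a possible array batch, parts the TCL1-AT arrays and WT 1 from WT 2 to 5. The 3445 features called between TCL1-AT 1, 3 and 5 and WT 2 to 5 kept a slope of 0.769 between TCL1-AT 2 and 4 and WT 1, which have like backgrounds, and 91.4% kept their sign. This argues against background as the whole cause, but rests on WT 1 as the only held-out control array. The pooling of the WT samples, the transplantation and the leukaemia itself stay open, as untested explanations.

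The higher MHC class II transcripts in cells sorted as low for MHC class II were the second pattern. With the background block, which sets the TCL1-AT arrays against WT 1 alone, the list's mean log2 difference was 1.47, against 1.53 without it. This argues against background level as the whole cause, but rests on that 1 control array. RNA of B or CLL cells, which express class II, may contribute, and the sort against lineage markers would be expected to remove such cells. The median of the 6 tested B cell markers was 0.288, below the class II median of 1.53. Of 15 such markers on the array, 9 were not detected on at least 5 arrays. Among these 9, Pax5, Cr2, Vpreb3 and Bank1 were detected on 0 TCL1-AT arrays and the others on 1 to 3. Only Cd22 had a WT level between 5 and 8, while the other tested markers were near the floor or already abundant. The share of RNA from such cells therefore cannot be told apart from a rise within monocytes. A difference in where the sorting gate fell and an effect of the leukaemia were not tested.

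Lower T cell and higher erythroid transcripts were the third pattern. A lower share of monocytes, with the mix of other cells unchanged, would raise the markers of every other cell type. The T cell markers changed by -0.717 (SE between arrays 0.0688) and the erythroid markers by 1.49 (SE 0.255), which argues against that case. A lower share with a changed mix of other cells cannot be excluded by these values. With the background block the T cell list's mean was -0.904, which argues against background level as the whole cause of the fall. That block sets the TCL1-AT arrays against WT 1 alone, so this mean rests on 1 control array. Unequal carry-over of T cells and erythroid cells through the sort, although a gate negative for lineage markers and positive for CD11b would be expected to remove T cells, and a change of these transcripts within monocytes, stay open as untested explanations.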

How the results depend on the processing

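The background block, the background covariate, leaving out TCL1-AT 3 and 4 together and median scaling over detected probes were chosen after the data were seen. A slide block was not run. Directions of the counts and lists below refer to TCL1-AT minus WT. The quantile settings without background correction, with normexp by maximum likelihood, cyclic loess, the series matrix, the mean over a gene's probes, array weights, and the trend and robust variances kept both counts of features within 1.5 times of 1828 and 2291. Median scaling called 991 higher, the background block 452 higher and 565 lower, of which 438 and 540 were among the original calls, and the background covariate 766 and 1048. A log2 difference of at least 1 left 270 and 260, by its own construction. Leaving out each array in turn gave 1438 to 2047 higher and 1880 to 2307 lower. The replicate numbers did not pair the arrays, with correlations of deviations from -0.17 to 0.20 and 1 of 5 TCL1-AT arrays correlating best with its own number, and the fit with the replicate number as a block called 1506 higher and 1982 lower and 8 lists.

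The 8 lists became 17 with median scaling, 15 without a detection filter and 17 with every probe by itself, 0 with an estimated correlation and 22 in fry, and 8 to 9 when each array was left out in turn. They became 11 with the mean over probes, without TCL1-AT 3 and 4, and with median scaling over detected probes. All 8 passed with every alternative to the fit, other than the erythroid list, not tested with the strict filter, and the cell cycle list, lost with the background block (adjusted p = 0.0509). Classical monocyte genes, lysosome genes, ribosomal proteins, pro-inflammatory cytokines, basophil markers, patrolling monocyte genes, immediate early genes, chemokines, inhibitory molecules, scavenger receptors and neutrophil markers passed under at least 1 alternative (adjusted p = 0.00011 to 0.0481). The cause was not tested.

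Values that changed sign had not been called, and the cause was not tested. The Fc receptor list's mean became 0.0237 with the strict filter, 0.0156 with the mean over probes, 0.0537 with the background block and 0.0299 with the covariate, and lay between -0.0453 and 0.0239 with each array left out, above 0 without TCL1-AT 2 or WT 2. Splenic macrophage markers became 0.0724 without background correction, 0.0577 by maximum likelihood, 0.213 with the strict filter and 0.0799 with every probe. The unfolded protein response became -0.0259, -0.0145 and -0.0886 in the first 3 of these settings, -0.0132 with median scaling and -0.00275 with the mean over probes. Cholesterol synthesis became 0.00911 with the strict filter and 0.00534 with every probe, and lay between -0.193 and 0.0363 with each array left out, above 0 without TCL1-AT 5. Glycolysis became -0.0227 with median scaling and -0.00701 without TCL1-AT 3 and 4, p53 targets 0.0366 with every probe and 0.00832 with the block, co-stimulatory ligands 0.102 with every probe, B cell markers -0.0324 with the strict filter and neutrophil markers 0.0121 with the block. Itgam became 0.121 with the covariate. S100a8 became 0.0115 with array weights, 0.251 with the block, 0.0192 with the covariate and 0.0669 without TCL1-AT 3 and 4, and lay between -0.162 and 0.0603 with each array left out, above 0 without TCL1-AT 4, and S100a9 became 0.133 with the block and 0.0336 without TCL1-AT 3 and 4. The difference in probes detected lay between -0.0776 (without WT 5) and 0.632 percentage points (without TCL1-AT 4) with each array left out (exact permutation p = 0.294 to 0.881).

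Of 3649 values of 136 named genes under alternatives, 3577 had the direction and call reported, 61 lost the call, 3 gained it and 8 changed direction, with 101 genes never changed, and the background block ended 27 calls and the covariate 11. Mean signal was 2.95 to 3.90 times the estimated background, which limits genes near the floor.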

Other observations

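All gene lists and genes in this part were chosen after values had been seen, 9 lists in all. The list tests below use only members outside the named genes and outside the 130 largest changes looked at in each direction. They are adjusted over the 8 lists with at least 3 such members. Some of these members also belong to fixed lists, such as Ifi35 (type I interferon response) and Psmb8 (MHC class I presentation), both called higher. The tests are therefore not independent of the results of those fixed lists.

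Of 15 such genes induced by FoxO transcription factors, 1 rose and 8 fell, at a mean log2 difference of -0.35 (camera adjusted p = 0.00817, and adjusted p = 0.0938 with an estimated correlation). Txnip, a thioredoxin-binding protein, fell by 1.07, Bcl2l11, which encodes BIM, by 0.99 and Sesn1 by 0.83, and another probe of Bcl2l11 was not called (-0.29). In the other direction, Gadd45a rose by 0.82, and Sod2, a member seen before, had risen by 1.29. Of the members seen before, Fbxo32 had fallen by 1.39, with another probe at -0.34 not called, and Ccng2 by 1.32, a call lost with the background block (-0.88, adjusted p = 0.121). Of 16 genes induced by glucocorticoids, 1 rose and 5 fell, at a mean of -0.28, and the list did not pass (camera adjusted p = 0.0776, and adjusted p = 0.131 with an estimated correlation). Per1 fell by 1.09 and Tsc22d3, which encodes GILZ, by 0.98, with another probe at -0.19 not called, while the metallothionein gene Mt1 rose by 0.63. Of the members seen before, Fkbp5, a chaperone of the glucocorticoid receptor, had fallen by 1.63 and Klf9 by 1.41. The FoxO and glucocorticoid lists share Ddit4, which had been seen, and Bcl6, which was not called.

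Of 32 proteasome subunits, 16 rose and 0 fell, at a mean log2 difference of 0.24 (camera adjusted p = 0.00019, and adjusted p = 0.0952 with an estimated correlation). The immunoproteasome gene Psmb10 rose by 0.71, a call lost with the background block (0.48, adjusted p = 0.136), and Psmc5 by 0.53, a call lost with median scaling (0.43, adjusted p = 0.0912). Of 16 genes of the Ifi200 family and other Ifi genes, 9 rose and 2 fell, at a mean of 0.27 (camera adjusted p = 0.00817, and adjusted p = 0.0952 with an estimated correlation).

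Lipid-associated macrophage genes (1 rose and 1 fell of 9, camera adjusted p = 0.52), circadian clock genes (1 and 3 of 10, 0.375), NRF2 and its targets (2 and 1 of 7, 0.735) and Toll-like receptors with their adaptors (3 and 4 of 14, 0.617) did not pass, and plasma cell genes had too few such members to test. With the members seen before, 2 of 16 lipid-associated macrophage genes rose and 7 fell, and 1 of 22 glucocorticoid-induced genes rose and 11 fell. The clock repressor gene Nr1d2, which had been seen before, fell by 1.40 and the clock output gene Dbp by 1.06.

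The unnamed probe ILMN_2688507 was at 4.08 to 4.12 on all WT arrays and at 6.26 to 10.33 on the TCL1-AT arrays, highest on TCL1-AT 3. It was not detected on any WT array, and was at least 10.2-fold higher in TCL1-AT (adjusted p = 0.00049), or at least 6.35-fold without TCL1-AT 3.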
